A study of Mus musculus with 124 samples.

How the data were processed

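RNA from T cells, B cells and monocytes sorted out of mouse blood was sequenced in 124 libraries, which carry the treatment labels PBS, EtOH or CBM, a sex and a batch. The deposited values are raw counts per gene, which the authors made and did not normalise. Per the labels' protocols, cDNA was made with the SMART-Seq kit for low input and libraries with the Nextera XT kit, and paired ends were sequenced on a NovaSeq. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, checked with FastQC, trimmed with BBDuk, aligned to GRCm38 with HISAT2 2.1.0 without mixed or discordant pairs, and counted with HTSeq 0.11.2, and genes without a count in any sample were removed. The notes name the annotation GRCh38.78, a human build, but 53360 of the 53465 gene identifiers (99.8%) were mouse genes of GENCODE M21, from which chromosome, start and end were taken. 3 lines of the table name no gene and 26 gene symbols that a spreadsheet had turned into dates were recovered by their identifier. The labels state no strand, so Xist and Tsix, other antisense pairs, and Tmem189, whose span overlaps Cebpb, cannot be told apart by strand. Counts of near-identical genes, such as Rps3a3, Trim12c, H2-T22, Hspa1a with Hspa1b and the haemoglobin genes, are uncertain since the same sequence can fit more than 1 gene.

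Libraries whose titles share a number and all labels (39 pairs) were compared by a chi-square per gene over genes with at least 20 counts (median 1.22, range 1.1 to 1.32, against a median of 22.44 between other samples of a group) and summed, which left 85 samples. Library totals in M (1000000 counts) ranged from 0.33 to 3.48 M (median 2.18 M, 86 libraries) in batch 1 and from 2.04 to 8.28 M (median 4.69 M, 38 libraries) in batch 2. 1 sample, JS23 of the EtOH T cells, lay under 1 M counts. Expression is given as counts per 1000000 of the summed sample (CPM), and scores are means of log2(CPM + 1) over a list. Labels were checked against Xist, the sum of 4 Y-linked genes and the marker scores of the 3 cell types, and 15 samples went against a label (13 by sex, 2 by cell type). None was relabelled. The level of 1738 olfactory and vomeronasal receptor genes, which blood cells hardly transcribe, served as a measure of background reads.

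Comparisons were fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15) in R 4.3.3. Fits were made within each cell type for EtOH against PBS and CBM against PBS with sex as a term, for the interaction of treatment and sex, and for female against male in batch 1 with treatment as a term and in CBM. Cell types were compared within PBS and within CBM with sex as a term. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the genes tested passed. SE values of log2 differences come from the fit. Gene lists (34, with 486 members of which 485 were matched) were tested with camera and fry of limma 3.58.1, with the preset correlation and with an estimated one, and adjusted over the lists and 3 cell types together. Members were also counted with p adjusted over the list alone. Scores and quality measures were compared by exact two-sided permutation tests on the difference of means, over every regrouping, and adjusted over the measures and 3 cell types of a comparison. Tables and these tests were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

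The groups, the tests of genes and lists, the lists themselves and the rule for named genes were chosen before the data were examined. So were the alternatives, apart from those that the closing section names as later, while the tests of scores and quality measures were added afterwards. The rule names, for EtOH against PBS, the 10 genes with the lowest p in each direction among those that passed, and adds, where fewer than 5 passed in a direction, the 5 with the lowest p that did not pass. It names up to 4 members of each list, the 5 with the lowest p per direction for CBM against PBS, sex and interaction, and the markers and the 5 with the lowest p for cell types. Predicted genes, pseudogenes and receptor gene segments of lymphocytes were counted and not named. Alternatives were DESeq2 1.42.0, its size factors in edgeR, limma voom with sample weights, no filter on low counts or a stricter one, single libraries, other terms in the model, leaving out samples that go against a label, and leaving out each sample in turn. The comparison of EtOH with PBS without the 14 PBS and EtOH samples that go against a label was set beforehand, and its use as a result of its own was decided after the labels had been checked.

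The procedure was tested on simulated data, in which 200 of the better expressed genes were changed in the real sample layout. Genes were drawn independently, without wrong labels or structure shared among samples. The rates that follow hold for data of that kind and may be too favourable here. For EtOH against PBS with all samples, edgeR recovered 93%, 97% and 88% of 4-fold changes and 30%, 88% and 43% of 2-fold changes in T cells, B cells and monocytes. Without the 14 samples it recovered 94%, 98% and 88% of 4-fold and 36%, 75% and 22% of 2-fold changes. For the interaction it recovered 6%, 76% and 2% of 4-fold changes, and for sex in batch 1 91%, 100% and 93%. It recovered 96%, 99% and 92% for sex in CBM, for CBM against PBS 96%, 99% and 94%, and for T cells against the other types 97% in PBS and 100% in CBM. Of the calls DESeq2 made, 17.22%, 12.26% and 15.96% were false in the 3 cell types, above the 5% sought. Those of limma voom were 7.25%, 4.32% and 4.8% false. Those of edgeR were 4.65%, 3.14% and 4.38% false with all samples and 7.8%, 4.95% and 3.51% false without the 14 samples. They were 14.29% false for the interaction in T cells, 5.3% for sex in CBM T cells and 5.47% for T cells against the other types in CBM.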

Results

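RNA was sequenced from T cells, B cells and monocytes that had been sorted by flow cytometry from the blood of mice. In the model of prenatal alcohol exposure, CD1 mice, an outbred stock, were injected with 4.0 g/kg of ethanol as a 25% solution in phosphate-buffered saline on embryonic days 16 and 17, and offspring blood was taken between postnatal days 35 and 40. The series set out to find blood RNA markers of neurocognitive impairment that prenatal alcohol exposure shares with maternal diabetes. The labels give the treatments EtOH, PBS and CBM. CBM is not explained by the labels, and its samples form sequencing batch 2, while PBS and EtOH samples form batch 1. The table held 53465 genes and 124 libraries, which were summed to 85 samples because 39 samples had been sequenced as 2 libraries. There were 6 PBS, 9 EtOH and 12 CBM samples of T cells, 8 PBS, 8 EtOH and 13 CBM samples of B cells, and 8 PBS, 8 EtOH and 13 CBM samples of monocytes. Total counts (in M, 1000000 counts) per T cell sample ranged from 3.37 to 6.03 M in PBS, 0.33 to 5.78 M in EtOH and 3.21 to 8.28 M in CBM. Those of B cells ranged from 2.02 to 4.87 M in PBS, 1.18 to 5.22 M in EtOH and 2.04 to 6.89 M in CBM, and those of monocytes from 1.33 to 5.51, 1.29 to 6.23 and 2.1 to 7.33 M. The labels do not say that samples come from separate animals, so the p-values measure only the spread between these samples.

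The 39 pairs of repeat libraries were near sampling noise. Over genes with at least 20 counts, the chi-square per gene between both libraries of a pair was 1.1 to 1.32, with a median of 1.22, against a median of 22.44 and a minimum of 3.01 over 385 pairs of libraries from different samples of the same group. All 39 pairs were closest to their own repeat, and each pair was counted as 1 sample.

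Each sorted fraction carried the transcripts of its cell type, and T cells and monocytes also carried those of natural killer cells. Cd3e, a signalling chain of the T cell receptor complex (GRCm38), was at 1010 ± 41.6 counts per 1000000 (CPM, mean ± SD) in PBS T cells (n = 6) and 1060 ± 191 in CBM T cells (n = 12), against 9.54 ± 4.82 in PBS B cells (n = 8). Cd79a, a signalling chain of the B cell receptor, was at 4350 ± 703 CPM in PBS B cells, 4240 ± 804 in EtOH B cells and 3930 ± 484 in CBM B cells. Lyz2, the lysozyme of myeloid cells, was at 24800 ± 6000 CPM in EtOH monocytes (n = 8) and 29100 ± 5980 in CBM monocytes (n = 13). In 2 samples the markers went against the label. The EtOH T cell sample JS29 had a T cell marker score (mean log2 of CPM + 1 over 15 markers) of 3.99 and a Lyz2 level of 20600 CPM. The PBS monocyte sample JS17 had a monocyte marker score of 3.43, a Lyz2 level of 172 CPM and a Cd3e level of 865 CPM. Ncr1, a receptor of natural killer cells, was at 146 ± 129, 242 ± 169 and 354 ± 294 CPM in PBS, EtOH and CBM T cells and at 539 ± 687, 364 ± 190 and 299 ± 180 CPM in the monocytes. In the B cells it was at 6.35 ± 5.39, 2.54 ± 1.16 and 3.68 ± 2.36 CPM. B cell transcripts also reached some PBS T cell samples, with Cd79a at 157 ± 245 CPM (n = 6) and up to 624 CPM.

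**Figure D1:**
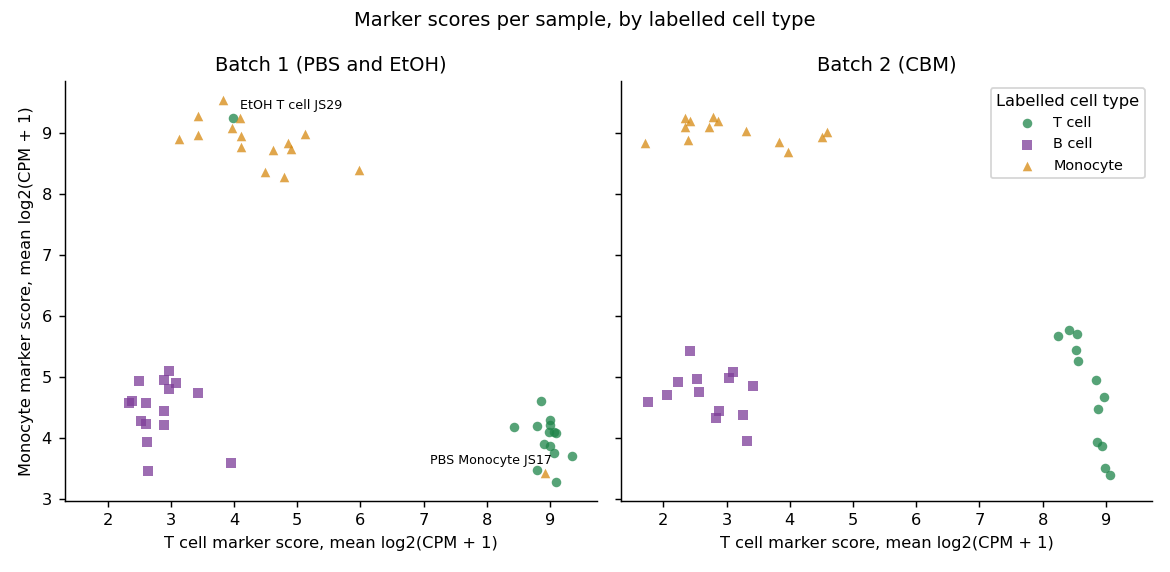
Each point is 1 sample, placed by its T cell marker score (horizontal axis) and monocyte marker score (vertical axis), both as mean log2(CPM + 1), with colours for the labelled cell type and a panel for each batch. JS29, labelled a T cell sample, has a T cell score of 3.99 and JS17, labelled a monocyte sample, has a monocyte score of 3.43.

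The genes of the sex chromosomes went against the sex label in 13 samples, 12 of them from batch 1. Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), had a median of 92.7 CPM in samples labelled female whose genes fitted the label. The summed CPM of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a median of 313.9 in fitting males. Among samples labelled male, Xist was at 50.9 CPM in JS32, 58.9 in JS44, 79.0 in JS15, 101.9 in JS16, 89.5 in JS33, 45.1 in JS34 and 66.0 in JS43, with Y-linked sums of at most 5.6. Among samples labelled female, the Y-linked sum was 363.2 CPM in JS20, 308.4 in JS18, 337.5 in JS21, 277.2 in JS19, 211.4 in JS22 and 374.2 in the T cell sample of CBM9, with Xist at no more than 3.5 CPM. By group, the labels were contradicted in 2 of 6 PBS T, 3 of 8 PBS B and 2 of 8 PBS monocyte samples, and in 2 of 9 EtOH T, 1 of 8 EtOH B and 2 of 8 EtOH monocyte samples. No sample was relabelled. With the markers of cell type, 15 samples went against a label. The comparison of EtOH with PBS is given both with and without them.

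**Figure D2:**
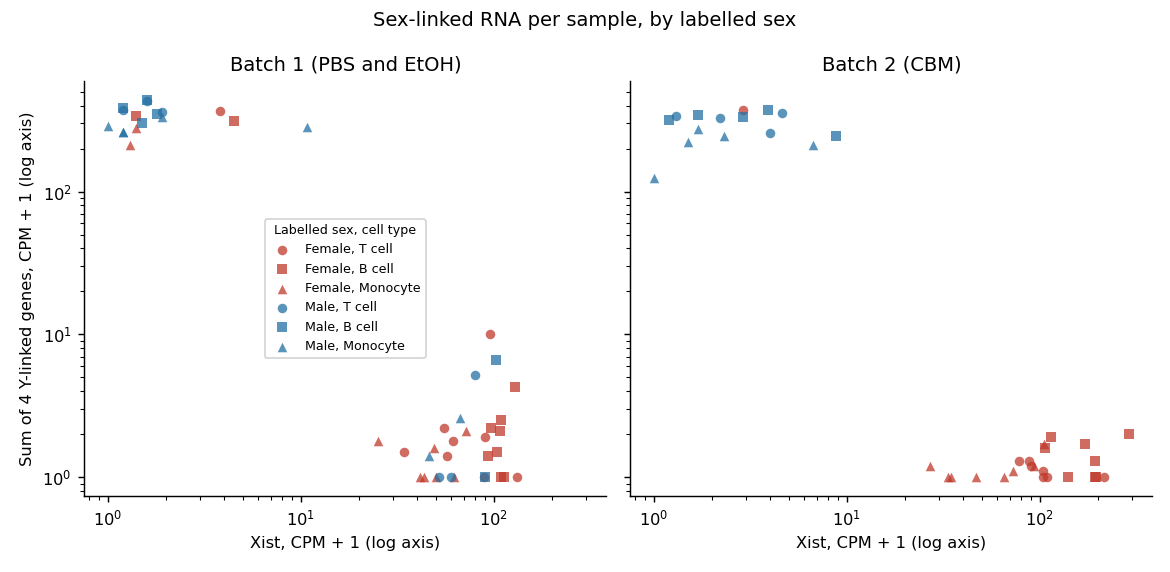
Each point is 1 sample, placed by its Xist level (horizontal axis) and the sum of 4 Y-linked genes (vertical axis), both as CPM + 1 on log axes, with colours for the labelled sex, shapes for the cell type and a panel for each batch. The 13 samples that go against their label lie among those of the other sex.

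The comparison of EtOH with PBS asks which blood transcripts differ in young mice exposed to alcohol before birth. In T cells with all samples, Il4ra, the receptor chain for interleukin 4, was at 380 ± 187 CPM in EtOH (n = 9) and 1140 ± 471 in PBS (n = 6), a log2 difference of -1.52 ± 0.32 (SE) that did not pass (adjusted p = 0.493, lower in 9 of 9 samples). Malt1, a signalling scaffold of lymphocyte activation, was at 79.1 ± 20.1 against 124 ± 14.3 CPM, the cold-inducible RNA-binding protein Cirbp at 108 ± 36.5 against 216 ± 72.2 CPM, and Zfp747 at 9.19 ± 3.48 against 18.3 ± 3.54 CPM. Tnxb, Ikbip, Pde5a, Acadsb and Gdpd3 had the lowest p on the higher side, with log2 differences of 4.32, 1.65, 1.97, 0.65 and 3.34. Cd79a also stood among the lowest p (log2 -3.31, 14.4 ± 6.45 against 157 ± 245 CPM), along with lower B cell markers at large. Their median was -2.16, with 0 of 14 measured passing over all genes, 8 lower adjusted over the list alone, and an adjusted p = 0.597 with an estimated correlation. Monocyte, nonclassical monocyte and neutrophil markers had medians of 1.82, 1.31 and 3.31 in this comparison, whose EtOH group holds JS29, with 0 of 13, 9 and 10 passing either way (camera adjusted p = 0.275, 0.511 and 0.0588). No gene passed with edgeR, which had 1272 of 13141 genes at an unadjusted p under 0.05, while DESeq2 called 76 and limma voom 327 on the same samples. With the marker scores of the other 2 cell types as terms, edgeR called 1773.

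In B cells with all samples, the transcription factor Cebpb was at 119 ± 28.7 CPM in EtOH and 230 ± 85.2 in PBS (n = 8 each, log2 -0.95 ± 0.21, lower in 8 of 8 samples). Rgs1, a regulator of G protein signalling, was at 17.7 ± 4.84 against 35.7 ± 12.4 CPM. Tmem189, whose annotated span overlaps Cebpb on chromosome 2, Itm2c and Traf4 had log2 differences of -0.77, -0.87 and -0.68. Pik3c2b, Slc38a9, Tarbp1, the histone methyltransferase gene Setdb1 and Zfp182 had the lowest p on the higher side, at 0.71, 0.48, 0.87, 0.52 and 0.58. None passed, with adjusted p between 0.659 and 0.67. With edgeR 0 genes passed and 955 of 13337 had an unadjusted p under 0.05, against 1 call by DESeq2 and 0 by limma voom. In monocytes, Ceacam2 (4.86), Cldn15 (1.83), the mast cell protease gene Prss34 (2.81), Itpripl1 (1.08) and Zfp229 (2.13) had the lowest p on the higher side of the log2 scale. On the lower side were Smad7, an inhibitor of TGF-beta signalling (-1.21), Dennd2d (-0.99), Rnf125 (-1.14), Rfk (-0.45) and Vps52 (-0.60), all at an adjusted p = 0.998. With edgeR 0 genes passed and 461 of 13596 had an unadjusted p under 0.05, with 2 calls by DESeq2 and 0 by limma voom.

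Over the fixed lists with all samples, camera with its preset correlation called 40 of 101 tests, and none held with an estimated correlation. Ribosomal protein genes had a median log2 difference of -0.46 in T cells, where 0 of 30 passed over all genes and 15 were lower adjusted over the list alone (camera adjusted p = 4.28e-19, and 0.425 with an estimated correlation). Erythroid genes had medians of -0.99, -0.98 and -0.72 in T cells, B cells and monocytes, each with 8 measured and 0 passing either way, and adjusted p = 0.597, 0.545 and 0.532 with an estimated correlation. In monocytes, whose PBS group holds JS17, 4 of 12 neutrophil genes were higher adjusted over the list alone and 0 over all genes. The neutrophil score was higher in EtOH by 1.68 with all samples and by 0.90 without the samples that go against a label. Ngp was at 4060 ± 4490 CPM in EtOH and 687 ± 524 in PBS (n = 8 each; adjusted p = 0.425 with an estimated correlation). In the same cells 4 of 4 Y-linked genes were lower adjusted over the list alone, in groups where sex genes contradicted 2 labels each (adjusted p = 0.425 with an estimated correlation). Among 36 differences of marker scores and quality measures, the dendritic cell score was 3.76 ± 0.248 in EtOH monocytes and 3.15 ± 0.538 in PBS monocytes (n = 8 each; exact permutation test, two-sided p = 0.0113, adjusted p = 0.266), and none passed after adjustment. T cell samples, summed over their libraries, held 3.24 M counts on average in EtOH and 4.97 M in PBS (exact permutation p = 0.0434, adjusted p = 0.388).

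The comparison was repeated without the 14 PBS and EtOH samples that went against a label, and its use as a result of its own was decided after the labels had been checked. The EtOH groups then held 5 females and 1 male in T cells, 6 and 1 in B cells and 5 and 1 in monocytes, and the PBS groups 2 females and 2 males in T cells and 2 and 3 in the others. In T cells of 6 EtOH against 4 PBS samples, Il4ra fell to 305 ± 55.8 from 1280 ± 464 CPM (log2 -2.33 ± 0.27), and the interferon gamma receptor chain Ifngr2 to 64.7 ± 22.8 from 302 ± 158 CPM. Gata2, a transcription factor of blood stem cells, mast cells and basophils, fell to 2.89 ± 2.5 from 30.2 ± 3.27 CPM (log2 -4.07 ± 0.48). The chemokine genes Ccl6 and Ccl9 fell to 22.3 ± 7.99 from 112 ± 47.6 CPM and to 5.88 ± 3.59 from 33.9 ± 9.09 CPM. Cebpb fell to 45.5 ± 13.1 from 138 ± 50.7 CPM (adjusted p = 0.00219). The kinase genes Plk3 and Stk11, the repressor gene Zbtb21 and the clock gene Per1 fell by 2.43, 1.95, 1.64 and 2.41 on the log2 scale. Higher were Magi1, a scaffold of cell junctions (20.6 ± 5.51 against 1.22 ± 1.24 CPM, log2 4.50 ± 0.58, adjusted p = 0.00264), the nonclassical MHC gene H2-T22 (2.52), Trim12c (2.01) and Mob3a (1.49, 353 ± 72.4 against 119 ± 33.6 CPM). Also higher were the condensin gene Ncapg (2.72), Ttyh2 (3.21), Gdpd3 (3.06), Pigh (1.40), the thromboxane receptor gene Tbxa2r (1.53) and Nedd1 (1.35). All 20 genes lay on the stated side of the PBS mean in 6 of 6 EtOH samples. In total 145 of 17619 genes passed with edgeR, 34 higher and 111 lower. Leaving out single samples moved that count between 31 (without the PBS female JS4; 32 without JS7, the other PBS female) and 283 (without the PBS male JS1), a term for the erythroid score left 3 calls, and DESeq2 and limma voom called 1051 and 1292.

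In the same T cells, of 18 immediate early genes, which cells switch on within minutes of a stimulus, 3 fell over all genes and 13 adjusted over the list alone. Egr1 fell to 44.2 ± 23.9 from 116 ± 25.9 CPM, Ier2 to 203 ± 56.4 from 437 ± 111 CPM and Nr4a2 to 2.39 ± 1.72 from 9.21 ± 4.72 CPM. The list median was -1.06, with a camera adjusted p = 1.92e-14, and this was the only list call in any cell type that held with an estimated correlation (adjusted p = 0.0481). List tests were not repeated without single samples, with the erythroid score as a term or on regrouped samples, so how far this call depends on them is not known. With all samples the median of these 18 genes in T cells was -0.19, with 0 passing either way (camera adjusted p = 0.00278, and 0.648 with an estimated correlation). Of 9 erythroid genes, 4 fell over all genes and 6 adjusted over the list alone. Hbb-bs, a beta chain of haemoglobin, was at 799 ± 378 against 2370 ± 1400 CPM and Alas2, the haem synthesis enzyme of red cell precursors, at 56.7 ± 30.9 against 185 ± 121 CPM (list median -2.33, camera adjusted p = 7.04e-14, adjusted p = 0.224 with an estimated correlation). Of 14 glucocorticoid-responsive genes, Per1 and Klf9 (log2 -2.21) fell, with 5 lower adjusted over the list alone (adjusted p = 0.224 with an estimated correlation). Of 30 ribosomal protein genes, 1 fell, Rplp1 (122 ± 24.8 against 251 ± 61.8 CPM), and 25 were lower adjusted over the list alone, with a median of -0.67 that became -0.62 with DESeq2 size factors (adjusted p = 0.345 with an estimated correlation). Of 16 clock genes Per1 and Nfil3 (log2 -1.21) fell, and 3 were lower adjusted over the list alone (camera adjusted p = 0.0159, and 0.267 with an estimated correlation). The glucose transporter gene Slc2a1 (-1.11) was the only one of 15 glycolysis genes to fall (1 lower adjusted over the list alone, camera adjusted p = 0.0535). The insulin receptor substrate Irs2 (-1.27) was the only one of 15 insulin signalling genes (3 lower adjusted over the list alone, camera adjusted p = 0.0302, and 0.267 with an estimated correlation). The cell death gene Bbc3 (-1.66) was the only one of 13 p53 targets to fall (1 lower adjusted over the list alone), a list whose median of -0.09 and mean of 0.25 differ in sign and which was not called (camera adjusted p = 0.337). Hmgcs1, a cholesterol synthesis enzyme, rose by 1.14, the only one of 18 in its list (2 higher adjusted over the list alone, camera adjusted p = 0.0975). Cell cycle genes had a median of 2.03, with 0 of 20 passing over all genes and 13 higher adjusted over the list alone, for example Cdk1 at 30.6 ± 33.6 against 3.3 ± 1.27 CPM (adjusted p = 0.511 with an estimated correlation). Markers of monocytes and B cells also had lower medians in these T cells, with 0 passing over all genes. Nonclassical monocyte markers had a median of -1.36 (4 of 9 lower adjusted over the list alone, camera adjusted p = 0.00856, and 0.267 with an estimated correlation). Monocyte markers had a median of -0.61 (3 of 14 lower adjusted over the list alone, camera adjusted p = 0.022, and 0.523 with an estimated correlation). B cell markers and MHC class II genes had medians of -0.66 and -1.07 (0 of 15 and 0 of 10 adjusted over the list alone, camera adjusted p = 0.464 and 0.146), whereas neutrophil and dendritic cell markers had medians of 0.40 and 0.93 (0 of 11 and 0 of 7 either way, camera adjusted p = 0.201 and 0.241). The dendritic cell score was 3.36 against 2.54 (exact permutation p = 0.0381, adjusted p = 0.274). The share of mitochondrial counts moved with the group, at 0.927 ± 0.0629% in EtOH (n = 6) and 1.18 ± 0.167% in PBS (n = 4; exact permutation p = 0.019, adjusted p = 0.274).

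B cells without the contradicted samples (7 EtOH, 5 PBS) also had lower Cebpb, which fell to 111 ± 20.5 from 273 ± 78.1 CPM (log2 -1.42 ± 0.20, adjusted p = 0.00391, 7 of 7 samples). Id3, an inhibitor of E proteins, fell to 54.3 ± 13.1 from 134 ± 46.6 CPM, Rgs1 to 17.5 ± 5.19 from 42.4 ± 9.85 CPM, and the ubiquitin ligase gene Rnf125 to 18 ± 10 from 112 ± 69.2 CPM. Hbb-bt, a beta chain of haemoglobin, fell to 111 ± 68.1 from 373 ± 289 CPM. Atmin, the polyamine synthesis gene Odc1, Tmem189, Taf5l and Gadd45a fell by 1.32, 1.25, 1.17, 0.93 and 0.82 on the log2 scale. Brms1l rose to 28.7 ± 4.08 from 12.2 ± 4.48 CPM (adjusted p = 0.00376). Magi1 (3.46), Trim12c (2.10), Mob3a (1.58), the retinol dehydrogenase gene Rdh12 (1.22), Gpbp1l1 (1.60), D11Wsu47e (1.47), Nabp1 (1.13), Vamp1 (1.18) and Edaradd (1.97) also rose on the log2 scale, Mob3a and Rdh12 in 6 of 7 samples and the others in 7 of 7. The share of mitochondrial counts was 0.903 ± 0.116% in EtOH and 1.05 ± 0.0803% in PBS (exact permutation p = 0.0366, adjusted p = 0.274). The B cell marker score was 9.72 ± 0.145 against 9.46 ± 0.151 (exact permutation p = 0.0152, adjusted p = 0.274). In total 597 of 14768 genes passed with edgeR, 156 higher and 441 lower. Leaving out single samples moved that count between 9 (without the PBS female JS8; 26 without JS5, the other PBS female) and 1381 (without the EtOH sample JS30), a term for the erythroid score left 0 calls, and DESeq2 and limma voom called 1151 and 1919.

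In the same B cells, of 30 ribosomal protein genes, 17 fell over all genes and 29 adjusted over the list alone, among them Rps18 (log2 -0.62), Rpl3 (-0.67, 122 ± 17.5 against 180 ± 15.8 CPM), Rpl11 (-0.66) and Rplp1 (-1.02). Their median was -0.56, or -0.53 with DESeq2 size factors (camera adjusted p = 6.96e-20, adjusted p = 0.267 with an estimated correlation). Of 9 erythroid genes, 7 fell over all genes and 8 adjusted over the list alone, with Hbb-bs at 1540 ± 939 against 3300 ± 1890 CPM (median -1.96, adjusted p = 0.224 with an estimated correlation). Of 14 glucocorticoid-responsive genes, 5 fell, including Klf9 (-1.67), the decoy interleukin 1 receptor gene Il1r2 (-3.15), Pik3ip1 (-1.51) and Klf13 (-0.46), and 8 were lower adjusted over the list alone (camera adjusted p = 3.44e-07, and 0.229 with an estimated correlation). Of 10 MHC class II genes, Cd74 (23700 ± 3080 against 33800 ± 2940 CPM), H2-Ab1 (log2 -0.82) and H2-DMb1 (-1.27) fell, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0159, and 0.511 with an estimated correlation). Immediate early genes Nr4a1 (-1.32), Nr4a2 (-3.33) and Ier2 (-0.79) fell out of 17, and Tnfaip3 (-1.14), Nfkbia (-0.52) and Birc3 (-0.63), of the NF-kB list, fell out of 17. Neither list was called (camera adjusted p = 0.0901 and 0.152; 4 lower and 1 higher adjusted over the list alone in each). Irs2 (-1.29) and Foxo1 (-0.86) fell in the insulin signalling list, Slc2a1 (-1.05) among glycolysis genes, Insig1 (-1.34) among cholesterol genes and Prdm1, the plasma cell regulator, to 5.85 ± 3.86 from 16.3 ± 4.49 CPM. These are single members and do not speak for their lists as a whole. Spib, a B cell transcription factor, rose by 1.12 (661 ± 304 against 254 ± 69.8 CPM). Of 9 alcohol and aldehyde metabolism genes, Aldh1b1 (-1.02) and Aldh9a1 (-0.48) fell, both also adjusted over the list alone (camera adjusted p = 0.234).

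Monocytes without the contradicted samples (6 EtOH, 5 PBS) changed in 11 of 15514 genes, 2 higher and 9 lower, each in 6 of 6 samples. Apoe, the lipid carrier apolipoprotein E, fell to 473 ± 356 from 2220 ± 719 CPM (log2 -2.81 ± 0.47, adjusted p = 0.0498), and the signalling ligand Wnt11 to 6.24 ± 3.59 from 28 ± 17 CPM. Trim30b (-2.71), Rabgef1 (-1.92), Errfi1, a feedback inhibitor of the EGF receptor (-1.69), Noct (-1.68), the metallothionein Mt1 (-1.65), the lamin gene Lmnb1 (-1.64) and Tmcc3 (-1.59) also fell. Ms4a2, the beta chain of the high-affinity IgE receptor, rose to 51.3 ± 22.7 from 15.5 ± 8.34 CPM, and the heat shock gene Hspa1a to 9.91 ± 8.41 from 3.13 ± 2.4 CPM (log2 2.73 ± 0.41). Birc5, Mcpt8, a basophil protease (83.6 ± 61.9 against 11.9 ± 3.74 CPM), Ccl4, H2-T22 and Gpr34 had log2 differences of 2.78, 2.84, 1.84, 2.68 and 2.27 that did not pass (adjusted p = 0.0597). Of 20 cell cycle genes 0 passed over all genes and 16 were higher adjusted over the list alone (median 1.40, camera adjusted p = 2.09e-17, adjusted p = 0.224 with an estimated correlation). Natural killer cell markers were 0 of 12 over all genes and 6 higher adjusted over the list alone (median 1.14, adjusted p = 0.285 with an estimated correlation), with Ncr1 at 370 ± 185 against 179 ± 177 CPM. T cell markers had a median of 0.92 with 0 of 15 passing either way (adjusted p = 0.422 with an estimated correlation). With all samples, JS17 among them, both medians had the other sign, at -0.42 and -1.16, again with 0 of 12 and 0 of 15 passing either way. Dendritic cell markers had a median of 0.72 with 0 of 8 passing either way (camera adjusted p = 0.00758, and 0.267 with an estimated correlation), and their score was 3.77 against 3.14 (exact permutation p = 0.0346, adjusted p = 0.274). Of 8 erythroid genes 0 passed over all genes and 7 were lower adjusted over the list alone (median -1.73, adjusted p = 0.224 with an estimated correlation), with Hbb-bs at 833 ± 501 against 1550 ± 824 CPM. Monocyte markers had a median of -0.36, with 0 of 15 passing over all genes and 3 lower adjusted over the list alone, for example Cd14 at 1500 ± 666 against 2810 ± 1030 CPM (adjusted p = 0.224 with an estimated correlation). Leaving out single samples moved the count of 11 between 0 (without the EtOH samples JS37, JS40 or JS55 or either PBS female, JS6 or JS9) and 107 (without the EtOH sample JS31). A term for the erythroid score left 0 calls, and DESeq2 and limma voom called 365 and 627.

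Type I interferon genes passed in no cell type (camera adjusted p = 0.32 in T cells, 0.445 in B cells and 0.0929 in monocytes; 0 of 23, 22 and 23 measured, over all genes and adjusted over the list alone). Without the contradicted samples camera called 34 of 102 list tests, 1 of them also with an estimated correlation. The rotation test fry called 7 for genes moving on balance one way and 45 for genes changing in either direction, and neither of these compares a list with other genes.

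T cells and B cells shared 80 genes that changed in the same direction without the contradicted samples, where 3.7 were expected by chance from 139 and 592 calls among 14032 genes tested in both, and 0 changed in opposite directions. The 14 shared higher genes included Magi1, Mob3a, Trim12c, Nabp1, Gpbp1l1, D11Wsu47e, Rab5b and Map7. The 66 shared lower genes included the transcription factors Cebpb, Klf9, Nr4a2, Crem and Maff, the haemoglobin genes Hbb-bs and Hba-a1, Irs2 and Slc2a1. Apoe fell in all 3 cell types, by 2.90 in T cells, 2.53 in B cells and 2.81 in monocytes on the log2 scale. Errfi1 also fell in all 3, and Ms4a2 fell in T cells by 2.99 but rose in monocytes by 2.13. No score of basophil or mast cell markers was made. For Ms4a2, Gata2 and Mcpt8, a change within the sorted type was therefore not told apart from other cells carried along. T cells and monocytes shared 2 genes in the same direction (0.06 expected) and B cells and monocytes 4 (0.23 expected). Log2 differences of T cells and B cells had a Pearson r of 0.697 across genes, which are not independent replicates, and cells of different type may come from the same mice. With all samples no genes were shared, since 0 passed in each cell type with edgeR.

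**Figure D3:**
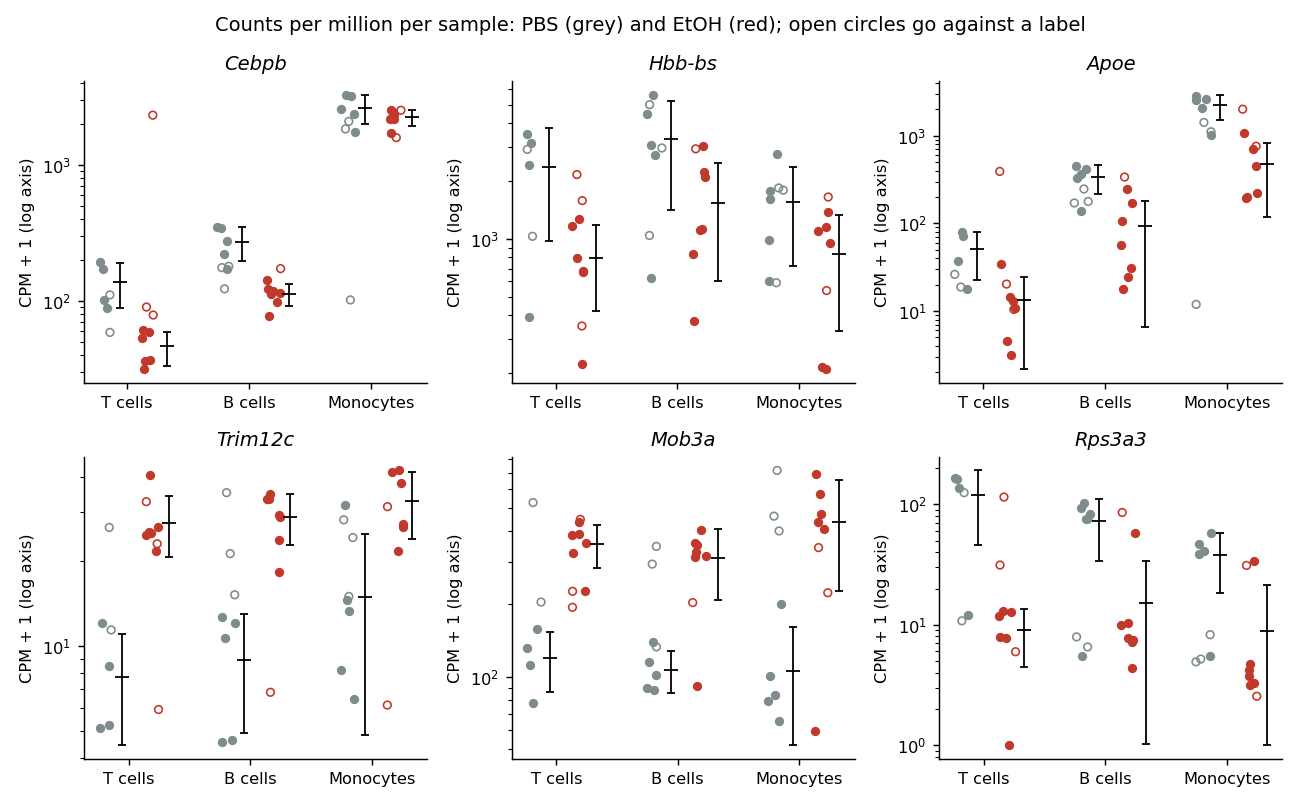
Levels of Cebpb, Hbb-bs, Apoe, Trim12c, Mob3a and Rps3a3 in each PBS (grey) and EtOH (red) sample of T cells, B cells and monocytes, as CPM + 1 on a log axis, where open circles are samples that go against a label and bars are mean ± SD of the filled circles. Cebpb in filled B cell samples was at 111 ± 20.5 CPM in EtOH (n = 7) and 273 ± 78.1 CPM in PBS (n = 5).

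Whether the ethanol difference itself differed between the labelled sexes was tested with an interaction term on all samples. Gspt2, an X-linked relative of a translation termination factor (chromosome X), was the only gene to pass, in monocytes. It was at 17.5 ± 3.18 CPM in PBS samples labelled female (n = 4) and 1.76 ± 0.945 in those labelled male (n = 4), against 11.8 ± 5.38 in EtOH samples labelled female (n = 5) and 20.9 ± 8.9 in those labelled male (n = 3). The sex genes went against the label in 2 of those 4 PBS samples labelled female (JS19 and JS22) and 2 of those 3 EtOH samples labelled male (JS34 and JS43). This is an interaction of -4.09 ± 0.55 on the log2 scale (edgeR adjusted p = 0.017). The call ended with limma voom (0 genes), without the contradicted samples (0 genes) and without any one of 11 single samples (JS31, JS34, JS40, JS43, JS55, JS11, JS14, JS19, JS22, JS3 or JS9), and DESeq2 called 2 genes. With edgeR 0 genes passed in T cells and 0 in B cells, where 395 of 15891 and 401 of 15094 had an unadjusted p under 0.05 and DESeq2 and limma voom also called 0. In monocytes 214 of 16520 did. Recovery of simulated differences was low for this test, at 6% of 4-fold changes in T cells, 76% in B cells and 2% in monocytes.

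Females and males by label were compared in each batch, a comparison that also checks the labels. In batch 1 with all samples, Xist was at 67.8 ± 37.7 CPM in T cells labelled female (n = 9) and 31.7 ± 35.4 in those labelled male (n = 6). Ddx3y, a Y-linked RNA helicase, was at 17.7 ± 49.4 against 72.3 ± 79.7 CPM. With edgeR 0 genes passed in T cells, 0 in B cells and 0 in monocytes, where 162 of 13141, 1464 of 13337 and 799 of 13596 had an unadjusted p under 0.05 and DESeq2 called 0, 123 and 2. Samples had been judged contradicted by Xist and the 4 Y-linked genes, so without them the calls on these genes were fixed by that choice and are no test of sex. Xist and Tsix were then higher in females and Ddx3y, Eif2s3y, Kdm5d and Uty lower in each cell type. Xist was then at 82.0 ± 27.5 CPM in T cells (n = 7) against 0.557 ± 0.337 in males (n = 3). It was at 107 ± 10.8 (n = 8) against 0.514 ± 0.231 (n = 4) in B cells, and at 48.2 ± 15.1 (n = 7) against 2.56 ± 4.83 (n = 4) in monocytes. T cells and monocytes had 6 such genes each and B cells 17. B cells added Myb, a transcription factor of blood progenitors (61.4 ± 26.1 against 16.2 ± 8.67 CPM), the proliferation marker Mki67 (8.07 ± 2.7 against 2.38 ± 1.38 CPM), Plxna1, Eps8, Coq7 and Magee2, all higher in females, and Clec2i (95.5 ± 20.5 against 168 ± 41.3 CPM) and Tagap, lower in females. These further B cell genes were named after their values had been seen. Most of these females were EtOH samples and most of the males PBS samples, and the CPM means pool both treatments. With treatment as a term, Myb differed by 1.40 ± 0.25 and Clec2i by -1.04 ± 0.17 on the log2 scale (edgeR adjusted p = 0.0422 and 0.0173). This fit was not repeated without single samples. X-linked Kdm6a, Kdm5c, Eif2s3x and Ddx3x did not pass.

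In CBM, B cells had 6 genes that differed by sex, Xist (175 ± 58.5 CPM in 8 females against 2.7 ± 3.04 in 5 males), Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty, with Xist at a log2 difference of 6.35 ± 0.50 (adjusted p = 1.91e-06) and Ddx3y at -11.08 ± 0.35. In total 352 of 16609 genes had an unadjusted p under 0.05 there. CBM monocytes had 5, namely Xist (5.60), Ddx3y (-10.38), Eif2s3y (-10.91), Kdm5d (-8.07) and Sgpp1, a phosphatase of sphingosine 1-phosphate. Sgpp1 was lower in females (19.5 ± 6.99 against 63.5 ± 17.6 CPM, log2 -1.71 ± 0.27, adjusted p = 0.0332). Sgpp1 no longer passed without any one of 8 samples (CBM1, CBM3, CBM4, CBM5, CBM6, CBM8, CBM9 or CBM11, with adjusted p from 0.0561 to 0.164), and the monocyte count fell to 4 without each of these but CBM11. Leaving out the CBM12 sample raised that count to 275, and DESeq2 called 587. In CBM T cells Xist was at 98.2 ± 58.2 CPM in 8 females and 2.02 ± 1.5 in 4 males, and with edgeR 0 genes passed, 717 of 15696 had an unadjusted p under 0.05 and DESeq2 called 9. Leaving out CBM9, whose genes are those of a male, gave 8 genes, the same 6 and the predicted Y-linked genes Gm28444 and Gm21719. The B cell and monocyte samples of CBM9 are labelled male, and only its T cell sample is labelled female.

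CBM and PBS samples differ in both label and sequencing batch, so the 2 cannot be told apart in what follows. In T cells, Gnas, a G protein alpha subunit, was at 114 ± 18.6 CPM in CBM (n = 12) and 822 ± 71.7 in PBS (n = 6; log2 -3.12 ± 0.11, adjusted p = 1.54e-13). Ankrd13a, the RNA methylation reader Ythdf1, the glycosyltransferase gene Galnt1 and the deubiquitinase gene Otulin were lower by log2 values of -3.80, -3.42, -3.31 and -3.88. Mllt6 (135 ± 28.8 against 29.2 ± 4.84 CPM), the cholesterol transporter gene Abcg1 (1.76), Zc3h4 (1.70), Itpripl1 (3.39) and Dpysl2 (1.93) were higher. In B cells, Cebpb was at 4.2 ± 1.98 CPM in CBM (n = 13) and 230 ± 85.2 in PBS (n = 8; log2 -5.96 ± 0.25, adjusted p = 8.49e-15). Gclc, Tmem64, Cited2 and Ube2m were at -3.01, -2.64, -3.62 and -3.25. The ribosomal genes Rpl37a (525 ± 145 against 87.6 ± 25.8 CPM) and Rpl39 (2.32), Zc3h4 (1.87), Ddx17 (1.59) and Mllt6 (1.93) were higher. In monocytes, Tmem189 (-4.38), Ythdf1 (-2.79), Ppp6r1 (-2.36), Yaf2 (-2.35) and Wac (-1.93) were lower. Higher were Rps2 (77.7 ± 14.1 against 11.4 ± 3.56 CPM), Itpripl1 (2.54), Klhl9 (2.01), Sgsh (1.80) and the splicing factor Prpf8 (1.27). All of these lay on 1 side of the PBS mean in every CBM sample. With edgeR 7432 of 15669 genes passed in T cells (3830 higher, 3602 lower), 5734 of 16157 in B cells (3020 higher, 2714 lower) and 3511 of 14603 in monocytes (1524 higher, 1987 lower). DESeq2 size factors moved the median of all genes by 0.1 in T cells, where 4391 were then higher and 2940 lower. The share of mitochondrial counts was 1.66 ± 0.523% in CBM B cells (n = 13) and 1.01 ± 0.113% in PBS B cells (n = 8; permutation test p = 0.000236, adjusted p = 0.0077). In monocytes the platelet score was 4.05 in CBM and 5.69 in PBS (permutation test, adjusted p = 0.0077), and the T cell and B cell scores were 3.06 against 4.79 and 1.94 against 3.14 (permutation test, adjusted p = 0.0464 for each). The PBS group there holds JS17, and these scores were not compared without it.

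The sorted types were compared with each other within PBS and within CBM, each type against the mean of the other 2. All 15 T cell markers were higher in T cells, all 15 B cell markers in B cells and all 15 monocyte markers in monocytes, in both PBS and CBM. In CBM, the T cell genes with the lowest p were Cd247, a T cell receptor chain (395 ± 44.7 CPM in 12 samples against 19.9 ± 16.5 in 26), Igfbp4 (log2 6.59), Cd27 (4.97), the co-receptor Cd6 (6.68) and Cd40lg (7.45), the ligand through which helper T cells act on B cells. Those of B cells were Cd79b (2860 ± 475 CPM in 13 samples against 16.7 ± 8.27 in 25), Gga2 (4.89), Cd79a (8.78), Vpreb3 (8.22) and the IgM receptor gene Fcmr (9.34). Those of monocytes were Plod3 (3.63), the peroxidase gene Gpx1 (3630 ± 566 against 562 ± 146 CPM), Creg1 (3.20), Ptpre (2.95) and Ralb (3.80). In PBS, T cells were led by the kinase gene Prkch (3.15), Fyb (2.20), Sntb1, Pdlim4 and Hcst, B cells by Strbp (2.10), Cd72 (3.01), Dmxl1, H2-Oa (4.11) and Snx2, and monocytes by Fyb (2.71), the lysosomal proteases Ctsd (2.41) and Ctsb (3.12), Smpdl3a and Id2. The monocyte marker Ly6c2, which also occurs on memory T cells, was higher in T cells than in the mean of the others by 1.46 in PBS and 0.86 in CBM. T cell markers were lower in CBM monocytes in 14 of 15 cases and changed in 0 of 15 in PBS monocytes, the group that holds JS17. With edgeR 5809 genes passed for T cells, 5887 for B cells and 7419 for monocytes in PBS, and 7264, 7076 and 8711 in CBM. For CBM B cells 2667 were higher and 4409 lower, but DESeq2 size factors, which moved the median of all genes there by 0.16, gave 3823 higher and 3607 lower.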

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

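The tests on contradicted labels and on the genes that differed between EtOH and PBS were chosen only after the result was seen, while the batch question and the regroupings of samples were set beforehand. Samples standing apart were found by the gap between the most extreme sample and its neighbour in groups of 4 to 10 samples, which singles out about 1 in 20 groups by chance and here singled out 19 of 204 (9.31%).

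Sex genes or cell type markers went against the label in 15 samples. RNA of both sexes mixed in 1 tube is argued against, since 0 of the 13 samples with contradicted sex carried both sets of genes, those present standing at 48.7% of their usual level or more and those of the labelled sex at 3.8% or less. Labels displaced along runs of sample numbers may account for part of the pattern, since 10 pairs of neighbouring numbers were both contradicted against a median of 4 in permutations (permutation p = 3e-05), but neighbouring numbers hold different cell types and may be 1 mouse with 1 wrong sex on record. An exchange between PBS and EtOH stays open. Over the genes called in both T and B cells, 8 of 12 sex-contradicted samples of batch 1 lay nearer to the mean of the other treatment (5 of 7 labelled PBS, 3 of 5 labelled EtOH). These samples took no part in choosing the genes. A wrong sex alone would not move a sample to the other treatment, which argues against it for those 8, but not for JS15, JS16, JS43 and JS44. Fitting samples lay nearer to the other treatment in 4 of 33 cases. The genes were called from those fitting samples, which leaves no rate to test against, and the labels name no litters. The samples nearer to the other treatment formed the unbroken runs JS17 to JS22 and JS29 to JS34 and included JS2 and JS14. JS17 carried T cell markers where JS29 is labelled a T cell sample. JS29 carried monocyte markers where JS17 is labelled a monocyte sample. Exchanging both runs in order would match the cell type of every sample in them. It would leave the sex of JS17, JS18, JS19 and JS29 contradicted, and would not touch JS15, JS16, JS43 and JS44. JS30 and JS31, inside the second run, fit their labels and stayed in the EtOH group. Without JS30 the B cell count that leaves out contradicted samples rose from 597 to 1381. Without JS31 the monocyte count rose from 11 to 107. The B cell count became 1147 without JS2, and the monocyte count 1 without JS14. Whether an exchange may bear on those results stays open, and no biological explanation was tested.

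Without those samples, 145 genes differed between EtOH and PBS in T cells, 597 in B cells and 11 in monocytes. Background reads are argued against as the whole cause, since with the receptor gene level as a term the called genes kept a median of 0.97 of their log2 change (0.91, 0.99 and 1 by cell type), although 63 of 145, 298 of 597 and 11 of 11 still passed as standard errors grew by factors of 1.05, 1.13 and 1.03. Red cell RNA cannot be told apart from the group, since with the erythroid score as a term the changes kept a median of 0.7 (0.95, 0.61 and 0.75) while standard errors grew by factors of 1.63, 1.54 and 1.61, so that 3, 0 and 0 of the genes passed. The sort for cell type did not keep such RNA out. With all samples, mean Hbb-bs ran from 898 CPM in EtOH monocytes to 3190 CPM in PBS B cells. Variants that differ between families also stay open, since of the genes shared by T and B cells 0 of 14 higher ones had another higher one within 1 Mb without overlapping it, against a mean of 0.29 in random sets (p = 1 from random sets), and 5 of 66 lower ones another lower one against 6.5 (p = 0.66), which excludes no unlinked variants. Both counts left out neighbours of opposite direction. Such pairs within 1 Mb were lower Cirbp with higher Mob3a on chromosome 10, and lower AC123830.1 with higher Trim12c on chromosome 7. The exposure to ethanol stays open as a biological cause and was not tested apart from these, since the labels name no litters.

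Up to 7432 genes differed between CBM and PBS, in T cells. Every CBM sample is of batch 2 and every PBS sample of batch 1, so the sequencing batch and the group cannot be told apart, and no sample in the table links the batches. What CBM mice underwent is not stated, so no biological explanation was tested.

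The EtOH T cell sample JS29 had a T cell score of 3.99 against 8.43 to 9.35 in the others, a mitochondrial share of 0.442% against 0.849 to 1.12%, and Acadsb at 4.24 against 4.7 to 5.15 on the log2(CPM + 1) scale that the following values share. The PBS monocyte sample JS17 had a monocyte score of 3.43 against 8.27 to 9.54, with Cldn15 at 0.241 (1.71 to 2.96 in the others), Smad7 at 5.69 (3.49 to 4.26) and Dennd2d at 7.99 (5.32 to 6.53). The PBS monocyte sample JS14 had receptor genes at a log2 CPM of 11.5 against 5.28 to 7.51. Among T cells, Tnxb was at 0.734 in PBS JS20 (0 to 0.237), and Il4ra at 9.75 in EtOH JS32 (7.74 to 8.6). In EtOH JS23, the sample with the fewest counts, Cd79a was at 4.98 (3.09 to 4.04) and Trim12c at 5.34 against 4.45 to 4.73 in the other samples that fit their labels. Among B cells, Slc38a9 was at 6.09 in PBS JS21 (5.56 to 5.79), Tarbp1 at 3.34 in EtOH JS42 (4.13 to 4.69) and Traf4 at 6.36 in EtOH JS30 (5.52 to 5.9). JS30 also had Magi1 at 2.55 (3.99 to 4.94), Mob3a at 6.52 (8.3 to 8.66) and D11Wsu47e at 3.88 (4.7 to 5.06) among EtOH B cells that fit their labels, and the EtOH monocyte sample JS31 had Rabgef1 at 6.61 (5.29 to 5.7). The ethanol difference of Gspt2 differed between the labelled sexes in monocytes by -4.09 on the log2 scale, by the interaction term. The sex genes contradict part of those labels, and the call ended without the contradicted samples, so no difference between the sexes is shown.

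The same samples were regrouped at random into groups of the same sizes. For EtOH against PBS with all samples, where 0 genes passed, every grouping is as high by construction (50 of 50 in each cell type), so this says nothing about chance. Other groupings called up to 2 genes in T cells, 546 in B cells and 7 in monocytes. Without the contradicted samples, chance could not be excluded in T cells, where 5 of 100 groupings called as many genes as the real 145 and the highest other 2797. A count so far above the real one points to a structure of these samples, whose nature was not tested. In B cells 1 of 100 groupings, the real one, called as many genes (real 597, highest other 419), and in monocytes 3 of 100 did (real 11, highest other 73). The 73, and the 546 with all samples, point to such a structure too. Random groupings seldom reached the real counts. They treat samples as exchangeable, however, and the labels name no litters, so a grouping by family is not excluded. The cell types were not adjusted for. Leaving out JS8 lowered the B cell count to 9, and leaving out JS6 the monocyte count to 0. For the interaction the real count of 0 in T cells leaves nothing to compare (50 of 50, highest other 0). In monocytes 2 of 50 groupings called as many genes as the real 1. The highest other was 67, from the only other grouping that called any gene, which was not looked into further. Chance stays open there, since the sex labels in this test are contradicted in part and the call ended without those samples. B cells, with 2 EtOH males, were not regrouped for the interaction. For sex in batch 1 (50 of 50 in each cell type, real 0, highest others 282, 1 and 0) and in CBM T cells (50 of 50, real 0, highest other 16) the real count of 0 again leaves nothing to compare. No other grouping reached the real count in CBM B cells (1 of 50, real 6, highest other 0) and CBM monocytes (1 of 50, real 5, highest other 1). These counts hold X- and Y-linked genes, which follow from the sex, apart from Sgpp1 in monocytes. They test the count as a whole and not Sgpp1. Nor did another grouping reach the real count for CBM against PBS (1 of 50 each, real 7432, 5734 and 3511, highest others 0, 1143 and 82). The same held for the cell types, which had been sorted to differ (1 of 25 each, real 5809, 5887 and 7419 in PBS and 7264, 7076 and 8711 in CBM, highest others 0, 0, 0, 0, 542 and 4). In all of these, the share reached is the lowest that so few groupings can give.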

How the results depend on the processing

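The alternatives to EtOH against PBS without the 14 contradicted samples, the removal of the 2 samples with contradicted cell type markers, and CBM against PBS and the cell types without contradicted samples were chosen only after the result was seen. So was the background level as a term in EtOH against PBS with all samples. For the changed results that follow the cause was not tested, except where fewer samples or a different number of genes tested enters by construction.

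For EtOH against PBS with all samples, where edgeR passed 0 genes in each cell type (1272, 955 and 461 at an unadjusted p under 0.05), DESeq2 called 76 genes in T cells, 1 in B cells and 2 in monocytes, and edgeR without a filter on low counts 3, 200 and 154. With each library as its own sample, which counts 1 sample more than once, it called 730, 225 and 17. Without the contradicted samples it called 145, 597 and 11. In T cells limma voom called 327, the scores of the 2 other cell types as terms gave 1773 (1 in B cells), CBM samples in the fit 6, and removal of JS29 alone, whose cell type markers go against the label, 1. Leaving out each other sample gave 0 in every cell type, so the counts ranged from 0 to 1 in T cells.

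Without the contradicted samples, DESeq2 called 1051, 1151 and 365 genes, limma voom 1292, 1919 and 627, and a term for the erythroid score left 3, 0 and 0. With samples under 500 CPM of receptor genes only, the counts were 279, 1246 and 60. Without a filter they were 762 in T cells and 430 in monocytes, without the sex term 242 and 2, and with the background level as a term 81 and 18. Leaving out 1 sample gave 31 to 283 in T cells (JS35 248, JS38 67, JS41 64, JS1 283, JS12 68, JS4 31, JS7 32). It gave 9 to 1381 in B cells (JS24 341, JS30 1381, JS39 295, JS42 355, JS54 315, JS10 307, JS13 346, JS2 1147, JS5 26, JS8 9). In monocytes it gave 0 to 107 (JS31 107, JS3 52, JS49 3, JS11 3, JS52 2, JS14 1, and 0 without JS37, JS40, JS55, JS6 or JS9).

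For the interaction, edgeR without a filter called 46 genes in B cells and 73 in monocytes. The single monocyte gene became 2 with DESeq2 and 0 with limma voom or without the contradicted samples, and leaving out 1 sample gave 0 to 1. For sex in batch 1, the fits without the contradicted samples called 6, 17 and 6 genes, DESeq2 123 in B cells and 2 in monocytes, and edgeR without a filter 232 and 341. Leaving out 1 sample gave 0 to 45 in B cells (JS36 1, JS16 45). For sex in CBM, T cells had 9 genes with DESeq2, 5 without a filter and 8 without CBM9 (0 to 8 over single samples). B cells had 11 without a filter (6 to 9 over single samples), and monocytes 587 with DESeq2 and 720 without a filter (4 to 275 over single samples, 275 without CBM12).

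CBM against PBS in T cells gave 12435 genes without a filter, which tests more genes. Without the contradicted samples it gave 6632, 7434 and 2935, and the cell types gave 6657, 6345 and 8452 in PBS and 7184, 7157 and 8610 in CBM, all within 1.5 times the counts reported. With the title number as a replicate block the cell types of CBM gave 7239, 7858 and 9481 genes. Samples of different cell types were also correlated by their deviations from the group means over 9595 autosomal genes. The 37 pairs with the same number had a median of 0.293 (-0.061 to 0.598, 32 over 0.1), against -0.025 over 444 other pairs. In both other cell types at once, the closest sample had the same number for 18 of 38 samples. No CBM5 sample could meet this, as CBM5 has no T cell sample. List calls fell to 0 with all samples and to 1 without the contradicted ones with an estimated correlation. Calls shared between 2 cell types, summed over the 3 pairs so that a gene can count more than once, were 0 with all samples, 19 at an unadjusted p under 0.01 and 86 without the contradicted samples.

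Some X-linked genes that did not pass changed sign. In batch 1, Kdm6a was at -0.01 in T cells without a filter and 0.57 in B cells without the contradicted samples, and Kdm5c at 0.04 in T cells without those samples. In monocytes Kdm5c was at 0.17 without a filter and 0.44 without those samples, and Ddx3x at 0.05 and 0.16. Ddx3x was at 0.14 in B cells without those samples and at 0.25 in CBM monocytes without a filter. Over single samples Ddx3x ranged from -0.07 to 0.22 in CBM monocytes, Eif2s3x from -0.10 to 0.16 in T cells and -0.01 to 0.36 in B cells. Kdm5c ranged from -0.23 to 0.09 in T cells, -0.11 to 0.18 in B cells and -0.12 to 0.10 in monocytes, and Kdm6a from -0.11 to 0.15, -0.28 to 0.04 and -0.20 to 0.28. Of 3361 alternative values of named genes, 2921 kept direction and side of the threshold, 239 no longer passed, 167 passed newly and 34 reversed. This total includes genes that had not passed and stayed so. For EtOH against PBS without the contradicted samples, leaving out single samples kept 163 of 200 values in T cells and 214 of 240 in B cells. In monocytes it kept 77 of 176, and 91 no longer passed. Gspt2 kept 5 of 16.

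DESeq2 size factors in edgeR kept every count of genes within 1.5 times. Removing samples under 1000000 counts or with few detected genes took none from B cells and monocytes. Every alternative fit set beforehand was run, while the regrouping of B cells for the interaction, also set beforehand, was not. JS23 of the EtOH T cells had the fewest counts, 0.33 M (1000000). Of 2-fold changes simulated for EtOH against PBS with all samples, 30% were recovered in T cells, 88% in B cells and 43% in monocytes, so changes of that size can go unseen at these depths and sample numbers.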

Other observations

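The test of Rps3a3 in this part was chosen only after the result was seen, as was the reporting of the fixed lists without the contradicted samples. NF-kB inflammatory genes in that comparison of EtOH with PBS had a median log2 difference of -0.78 in T cells, with 0 of 17 passing over all genes and 5 lower adjusted over the list alone (camera adjusted p = 9.12e-06, and 0.267 with an estimated correlation). Ccl4 was at 17 ± 8.45 CPM in EtOH T cells (n = 6) and 54.3 ± 16.9 in PBS T cells (n = 4), and Tnfaip3 at 1690 ± 346 against 3160 ± 496 CPM. In monocytes the median of this list was -0.30 and its mean 0.10, of opposite sign, with 0 of 20 passing over all genes and 4 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.99). Ccl3 was at 403 ± 227 CPM in EtOH monocytes (n = 6) and 124 ± 62.4 in PBS monocytes (n = 5), and Il6 at 29.4 ± 11.6 against 7.73 ± 4.77 CPM. No difference between cell types was tested.

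Mitochondrially encoded genes had medians of -0.61 in T cells, -0.34 in B cells and -0.14 in monocytes, with 10 measured in each. Over all genes 0 passed in T cells, mt-Nd5 alone fell in B cells (480 ± 85.5 against 668 ± 47.6 CPM) and 0 passed in monocytes. Of the list, 6, 6 and 0 were lower adjusted over the list alone (adjusted p = 0.357, 0.511 and 0.779 with an estimated correlation). Naive T cell genes had a median of -0.44 in T cells, with 0 of 10 passing over all genes or adjusted over the list alone. Ccr7 was at 2460 ± 860 against 3760 ± 908 CPM (adjusted p = 0.511 with an estimated correlation). In monocytes 0 of 14 glucocorticoid-responsive genes passed over all genes and 5 were lower adjusted over the list alone. Il1r2 was at 298 ± 328 against 1600 ± 612 CPM and Klf9 at 43.7 ± 16.5 against 85.6 ± 36.1 CPM (adjusted p = 0.345 with an estimated correlation). Of 15 clock genes in monocytes 0 passed over all genes and 4 were lower adjusted over the list alone. Bhlhe40 was at 189 ± 46.2 against 336 ± 58.3 CPM (adjusted p = 0.229 with an estimated correlation). Of 15 heat shock genes in monocytes 1 rose over all genes, Hspa1a, and 4 were higher adjusted over the list alone (camera adjusted p = 0.000359, and 0.405 with an estimated correlation).

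Rps3a3, a processed pseudogene on chromosome 13, stood at 2 separate levels across the CBM samples, with a lowest value of 49 CPM among the high samples and a highest value of 7.41 CPM among the low ones. Equal CBM numbers may mark cells of the same mouse, since for 13 of 13 numbers the samples of every cell type lay on the same side of 20 CPM, 6 of them above it. Permuting the levels within cell types gave at most 11 numbers alike (permutation p = 1e-05, the smallest these permutations can give). An inherited variant is a candidate explanation of the 2 levels and was not tested. Both levels also occurred in batch 1, for example at 101 CPM in JS5 and 4.52 CPM in JS13 among PBS B cells and at 57.1 CPM in JS30 and 3.41 CPM in JS42 among EtOH B cells. Rps3a3 was 1 of the 66 genes lower in EtOH in both T cells and B cells, at log2 differences of -3.87 and -2.91.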
